A study of Escherichia coli with 6 samples.

How the data were processed

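RNA from zinc-limited and zinc-adequate chemostat cultures was compared on 6 2-colour arrays, 2 for each of 3 runs. Per the labels' protocols, random hexamers primed reverse transcription of 15 to 20 µg of RNA in the presence of Cy3 or Cy5 nucleotides, and each array received 1 RNA in each dye. The value used is the authors' deposited log ratio of the channels of each array, taken here as log2 because the values run on both sides of 0 with medians near 0. The scanner, background correction, normalization, treatment of repeated spots, log base and numerator of the ratio are not given in the sources used here. The array medians of the deposited values were 0.051 (1A), 0.040 (1B), 0.019 (2A), -0.013 (2B), -0.022 (3A) and 0.00084 (3B), so the arrays appear to have been centred before deposit, and their SDs were 0.732, 0.666, 0.623, 0.526, 0.513 and 0.574. Scale, centring and direction thus stay unknown beyond what the values show. Scanner files were not used here, so signal over background could not be examined and no filter on dim spots was applied.

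Of 4608 features, 290 had no value on any array, 4318 had a value on all 6 and 0 on only some. The platform annotation gave 1 gene symbol for 4073 of the features with values, several for 0 and none for 245. Symbols were updated through the gene identifier against the RefSeq annotation of assembly ASM584v2, which held 4086 of 4087 named features and changed 197 symbols. Features of 1 gene were averaged, which concerned 47 genes, and gave 4026 named genes and 245 unnamed features, 4271 tested in all. Unnamed features carry their position on the array as a name. No probe coordinates were used, so no genome positions are printed.

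Each array was centred on its median. Arrays A and B of a run share the run number in their titles and were treated as a dye swap of the same pair of RNAs, so they were averaged, which left n = 3 run means. Titles number the runs and arrays, but it is taken, not stated, that a run number marks a separate pair of cultures, and p-values measure the spread between these runs. In R 4.3.3, limma 3.58.1 fitted the mean of each gene with lmFit and tested it against 0 with eBayes, 2-sided, with Benjamini-Hochberg adjustment over the 4271 genes and features and a threshold of 0.05. With 3 values an exact test by sign flips cannot give a p under 0.25, so the moderated fit, which pools the spread over genes, was used throughout. A second count took genes with an absolute log2 ratio of at least 1 and an unadjusted p under 0.05. The difference A minus B of each run was fitted in the same way.

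A set of 20 gene lists with 576 members, 568 of them measured, was fixed before the data were examined. Members not measured included ykgO, flgA, gadA, cpxP, phnE, tisB and araH. Each list was tested with limma's camera with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the 20 lists, and again with camera's estimated correlation and with fry. Adjusted values over each list alone were computed beside those over all genes. The rule for naming genes was also fixed then: all measured Zur regulon genes, up to 10 genes on each side of 0 that passed the test with the same sign in all runs, with places filled by the smallest unadjusted p among genes with an absolute log2 ratio of at least 1 and the same sign in all runs, 2 to 4 members with the smallest p of each list described, and the mdtABCD-baeSR operon, fliD, rpmE and rpmJ. Of each list the 2 members with the smallest p in each orientation are named, and members that passed adjusted over their list alone were named besides, after their values were seen. znuA, ykgM and zinT fall under more than 1 part of the rule. Values are means of the 3 run means ± SD unless another value is named.

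The rule for direction, also set beforehand, compared the correlation of arrays A and B in each run with 3 possible orientations, and prescribed the values as deposited with no settled direction for any other outcome, which is what occurred. Turning the sign of array 3B, leaving that array out and centring each print block on its median were added after the data were seen. Alternatives set beforehand were no centring, scaling of the arrays to one spread, all 6 arrays with the run as a block or as if independent, a dye term, only the A or only the B arrays, leaving out array 1B, orientations by the labels' dyes and channels, requirements on missing values, a robust or unmoderated variance, an adjusted p under 0.1, features tested singly and leaving out each run.

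The gene test was checked on simulated run means for 4271 genes drawn from the variances fitted with array 3B turned. With 200 changed genes it recovered 81.2%, 99.4% and 99.8% of those changed by a log2 of 1, 2 and 3, and called 0.26% of unchanged genes. With 6 changed genes it recovered 5%, 91% and 99%. The simulated genes were independent, the spread of a gene was equal in all runs and the dye part cancelled exactly. None of this is given for the real arrays, so recovery there may be lower.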

Results

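Escherichia coli MG1655, a standard laboratory strain, was grown in pairs of glycerol-limited chemostats, vessels that are fed fresh medium at a constant rate so that growth settles at that rate. One vessel of a pair received adequate zinc (6.14 µM zinc oxide), and the other received medium without added zinc from which traces of the metal had been stripped. Cultures were kept at 37 °C and a dilution rate of 0.1 per h, and RNA was taken after 50 h. RNA from both vessels was labelled with the dyes Cy3 and Cy5 and hybridised together, so that each array gave a ratio between zinc-limited and zinc-adequate cells. The series held 3 chemostat runs with 2 arrays each, A and B, named 1A to 3B here. Values were present on all 6 arrays for 4318 of 4608 array features, which made 4271 genes or unnamed features. The comparison asks which transcripts differ in level between cells starved of zinc and cells supplied with it. Its precision is limited by the number of runs, and the median standard error of a gene's mean log2 ratio was 0.18.

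The direction of the deposited ratios could not be settled. The labels place the zinc-limited RNA in Cy5 on arrays 1A, 1B, 2A and 3A and in Cy3 on 2B and 3B, and do not say which RNA is the numerator. Across features, which are not independent replicates, arrays A and B correlated at r = -0.05 in run 1, -0.22 in run 2 and 0.48 in run 3, a set of signs that matched none of the orientations laid down beforehand. Arrays 2B and 3B, which the labels orient alike, correlated at -0.31. All signs below are therefore those of the deposited ratio, and neither sign is read as higher RNA in zinc-limited cells. The tests of genes and gene lists are given as deposited and again with the sign of array 3B turned, a setting chosen after the data were seen, because large ratios of zinc-uptake genes had the opposite sign on that array. The base of the logarithm is not stated either and was taken as 2, on which all fold sizes depend.

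**Figure D1:**
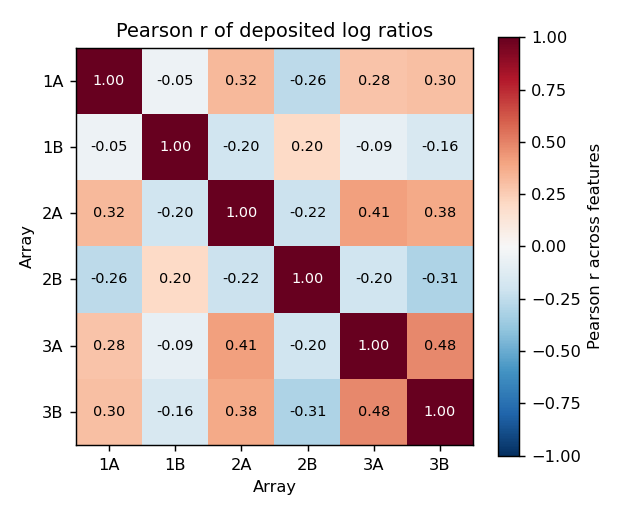
Pearson correlation across array features between the deposited log ratios of each pair of the 6 arrays (both axes: array, with the run number and the array letter; colour scale: Pearson r, no unit). Arrays 1A, 2A, 3A and 3B correlated with one another at 0.28 to 0.48, whereas 1B and 2B correlated with each other at 0.20 and with those 4 arrays below 0.

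The Zur regulon, the genes for zinc uptake and zinc sparing that the zinc-sensing repressor Zur controls, held the gene farthest from a ratio of 1 in both orientations. zinT (b1973), which encodes a periplasmic zinc-binding protein, had log2 ratios between -3.96 and -2.58 on 5 arrays and 2.86 on array 3B. With array 3B turned its mean was -3.19 ± 0.66 (SD, n = 3 runs), a 9.12-fold difference, and limma's adjusted p was 0.0168, with the same sign in 3 of 3 runs. As deposited, its mean was -2.24 ± 2.05 with an adjusted p of 0.581. The orientation of array 3B was chosen from the signs of these same genes, so their shared sign and smaller spread after turning are partly built in. With array 3B left out, also chosen after its signs were seen and so no independent check, the mean of zinT was -3.18 and its adjusted p 0.015. znuA (b1857), the periplasmic zinc-binding part of the high-affinity uptake system ZnuABC, lay between -2.30 and -0.97 on the same 5 arrays and at 2.39 on 3B. ykgM (b0296), a ribosomal protein L31 paralogue that needs no zinc, lay between -2.73 and -0.51 and at 1.09. pliG (b1178), an inhibitor of g-type lysozyme, lay between -1.60 and -0.20 and at 1.31.

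These 3 genes did not pass the test over all genes. With array 3B turned, znuA averaged -1.67 ± 0.59 (adjusted p 0.25), ykgM -1.38 ± 0.75 (adjusted p 0.753) and pliG -1.0 ± 0.09 (adjusted p 0.25), and as deposited they averaged -0.88 ± 1.41, -1.02 ± 1.26 and -0.56 ± 0.69. znuC (b1858), the ATPase of the uptake system, was below 0 on all 6 arrays, array 3B included, between -1.24 and -0.12, and averaged -0.57 ± 0.18 as deposited and -0.49 ± 0.10 with 3B turned. znuB (b1859), its membrane part, had both signs, between -0.38 and 0.85. The L36 paralogue gene ykgO was not measured. Adjusted over the list alone, 5 of the 6 measured members (zinT, znuA, pliG, ykgM and znuC) passed with array 3B turned, where the choice of orientation favours them, and 2 (zinT and znuC) as deposited. With array 3B left out, a choice that favours them in the same way, the same 5 passed over the list alone.

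As a group, the 6 Zur genes had a median log2 ratio of -1.19 with array 3B turned, with 6 of 6 below 0, and of -0.72 as deposited, with 5 of 6 below 0. In limma's camera test against all other genes, which presets the correlation between genes, the adjusted p was 8.97e-12 and 0.00457. With array 3B left out the median was -1.10, with 6 of 6 below 0 (camera adjusted p 4.32e-08). Since the signs of these genes on array 3B led to turning it and to leaving it out, the values of both settings depend on the outcome, and only those as deposited do not. With an estimated correlation the adjusted p was 0.487 with 3B turned and 0.52 as deposited, and fry, which tests a list against no change, gave an adjusted p of 0.194 and 0.368, so neither of these tests called the list, nor any other of the 20 lists. A call lost under an estimated correlation need not mean correlated genes. With 3B turned, the list for glycerol use had an estimated correlation of -0.043, below the preset 0.01. Its unadjusted camera p still rose from 0.00271 to 0.0809. Every other list that camera called had an estimate above the preset. As deposited these estimates ran from 0.083 (ribosomal proteins) to 0.36 (aerobic respiration), with 0.279 for the Zur list. With 3B turned they were 0.080 (Zur), 0.103 (ribosomal proteins) and 0.17 (RpoS). For those lists correlated genes may account for the lost call. The camera call of the Zur list as deposited was also lost without run 1 (median -0.37, adjusted p 0.0651), without run 2 (median -0.68, adjusted p 0.0604), on the B arrays alone (median -0.45, adjusted p 0.131) and with the arrays turned by the labels' channels (median -0.30, adjusted p 0.204). The call for zinT with 3B turned was lost on the A arrays alone, without array 1B, without run 3 and without limma's variance moderation. Its adjusted p ranged from 5.6e-05 to 0.18 over 15 alternatives. These do not include the unmoderated fit, for which only the lost call is given.

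**Figure D2:**
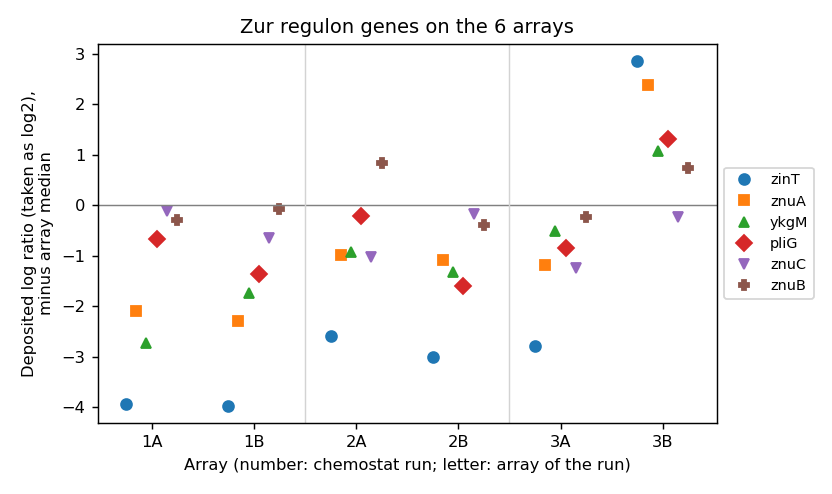
Deposited log ratio of each measured Zur regulon gene on each array, minus the array's median (y axis, taken as log2), against the array (x axis, number for the run and letter for the array); each point is 1 gene on 1 array. zinT lay between -3.96 and -2.58 on 5 arrays and at 2.86 on array 3B, and znuA, ykgM and pliG also changed sign there, whereas znuC stayed below 0.

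Over all genes, zinT was the 1 gene of 4271 past an adjusted p of 0.05 in limma's test with array 3B turned, and 0 genes passed as deposited, where the smallest adjusted p was 0.581. At an unadjusted p under 0.05 there were 205 genes with 3B turned and 329 as deposited, against 213.6 by chance. If 3B is an unturned dye swap, the deposited mean of run 3 keeps a dye effect, so the 329 need not reflect zinc. Genes are not independent, so neither count can be judged by its distance from 213.6. Without moderation of the variances the fit called 0 genes in both orientations. The count with 3B turned was 0 without run 3 and 3 without run 2. On simulated run means with the spread found with 3B turned, the test recovered 5% of genes changed by a log2 of 1 and 91% of those changed by a log2 of 2 when 6 genes changed, and 81.2% and 99.4% when 200 genes changed. These rates hold for independent genes with fully cancelled dye effects, and recovery on the real arrays may be lower.

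Genes with an absolute log2 ratio of at least 1 and an unadjusted p under 0.05 numbered 10 with array 3B turned, 9 of them below 0, and 9 as deposited, 5 above 0 and 4 below. With 3B turned, the genes below 0 were zinT, znuA, ykgM, yciQ (b1268, -1.33 ± 1.08), yjeN (b4157, -1.14 ± 1.18), uhpB (b3668, -1.07 ± 1.33), ybcH (b0567, -1.03 ± 1.11) and the unnamed features 3.3.10.8 (-1.44 ± 0.50) and 3.3.16.8 (-1.03 ± 0.47). uhpB encodes the sensor kinase for sugar phosphate uptake. The 1 above 0 was the unnamed feature 3.1.2.8 (1.07 ± 0.88). As deposited, the genes above 0 were hdeB (b3509, 1.00 ± 0.23), which encodes a periplasmic acid-stress chaperone, cysK (b2414, 1.02 ± 0.56), which encodes a cysteine synthase, melR (b4118, 1.07 ± 1.16), the regulator of melibiose use, yibG (b3596, 1.06 ± 0.66) and the unnamed feature 1.1.4.8 (1.03 ± 0.65). Those below 0 were zinT, yciI (b1251, -1.04 ± 0.18), yciQ (-1.40 ± 0.96) and the unnamed feature 3.4.16.9 (-1.46 ± 0.91). Except for zinT with 3B turned, none of these passed the adjusted test. Leaving out a run gave 11 to 36 such genes with 3B turned and 36 to 41 as deposited, and leaving out array 3B gave 20. The SDs cover run means and hide differences between the arrays of a run. yciI lay at -3.06 on array 2A and 1.11 on 2B, and yibG at -0.36 on 1A and 3.95 on 1B. Feature 3.1.2.8 lay at -0.71 on 2A and 4.39 on 2B, and 3.3.16.8 at -4.14 on 1A and 1.00 on 1B. melR kept its sign but rests mainly on 4.13 on 3B. As deposited, cysK, yciQ, 1.1.4.8 and 3.4.16.9 also kept one sign on every array. With 3B turned, zinT, znuA, ykgM, yjeN, uhpB and 3.3.10.8 did.

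Ribosomal protein genes lay above 0 as a group. The median of the 54 genes was 0.30 as deposited, with 48 above 0 (camera adjusted p 1.38e-09), and 0.16 with array 3B turned, with 44 above 0 (camera adjusted p 6.62e-06). With an estimated correlation the adjusted p was 0.52 and 0.525. The members with the smallest p were rplE (0.69 ± 0.37) and rplN (0.73 ± 0.47) as deposited, and rpsA (0.50 ± 0.09) and rpmG (0.46 ± 0.07) with 3B turned. No member passed the gene test, over all genes or adjusted over the list alone. The list also differed between the arrays of a run, with medians of 0.41, 0.62 and 0.42 on the A arrays and of -0.04, -0.06 and 0.48 on the B arrays. On the B arrays alone the call was lost as deposited (median 0.13, camera adjusted p 0.131), and with 3B turned the median was reversed, at -0.22 (camera adjusted p 0.0132).

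Genes of the general stress response under the sigma factor RpoS and of acid resistance also lay above 0. Of 29 measured, 24 were above 0 in both orientations, with a median of 0.32 as deposited (camera adjusted p 4.23e-07) and of 0.24 with 3B turned (camera adjusted p 1.18e-05). The adjusted p with an estimated correlation was 0.52 and 0.525. gadC, an exchanger of glutamate for its decarboxylation product, averaged 0.97 ± 0.34 as deposited and 0.64 ± 0.27 with 3B turned, and gadB, a glutamate decarboxylase, averaged 0.91 ± 0.51 and 0.55 ± 0.34. The acid-stress chaperone gene hdeB averaged 1.00 ± 0.23 and 0.61 ± 0.54. Adjusted over the list alone, 5 members (hdeB, gadC, hdeD, gadB and dps) passed as deposited and 0 with 3B turned. With 3B turned the list's call was lost without run 1 (median 0.11, adjusted p 0.148), and on the B arrays alone the median was reversed, at -0.13 (adjusted p 0.687).

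The genes for use of glycerol and glycerophosphate, the carbon and phosphate sources in the medium, had a median of 0.16 with array 3B turned, with 16 of 22 above 0 (camera adjusted p 0.0135), and of 0.15 as deposited, with 14 of 22 above 0 (adjusted p 0.166). glpD, the aerobic glycerol 3-phosphate dehydrogenase, averaged 0.42 ± 0.26 with 3B turned, and glpB, part of the anaerobic enzyme, 0.50 ± 0.39. As deposited, the members with the smallest p were dhaM (-0.53 ± 0.32), of dihydroxyacetone use, and tpiA (0.47 ± 0.31), triose phosphate isomerase. With an estimated correlation the adjusted p was 0.525 with 3B turned. That call was lost without run 2 (adjusted p 0.0721), without run 3 (adjusted p 0.0693), without array 1B (adjusted p 0.164) and without array 3B (adjusted p 0.0886), and on the A arrays or the B arrays alone (adjusted p 0.447 and 0.0957).

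Energy metabolism and heat shock lists passed only as deposited. The 30 genes of aerobic respiration and ATP synthase had a median of 0.21 as deposited (27 above 0, camera adjusted p 0.000243) and of 0.05 with 3B turned (19 above 0, adjusted p 0.287). The 17 genes of the citric acid cycle and glyoxylate shunt had medians of 0.28 (14 above 0, adjusted p 0.00217) and 0.04 (9 above 0, adjusted p 0.59), and the 18 heat shock genes had medians of 0.17 (16 above 0, adjusted p 0.00657) and 0.07 (11 above 0, adjusted p 0.287). For each of these 3 lists as deposited the adjusted p with an estimated correlation was 0.52. The respiration medians were 0.26, 0.41 and 0.35 on the A arrays and -0.19, -0.13 and 0.45 on the B arrays. Those of the citric acid cycle were 0.06, 0.50 and 0.14, and 0.04, -0.004 and 0.58. Array 3B thus raises both medians as deposited. With it left out both kept a camera call (adjusted p 0.00507 and 0.0431), but run 3 then rests on its A array, with no second array to balance the dyes. With 3B turned, both lists were higher on the A than on the B arrays, by medians of 0.58 and 0.54. The kept calls therefore cannot tell a dye effect from an effect of zinc. As deposited, nuoK and nuoB of respiratory complex I averaged 0.56 ± 0.11 and 0.50 ± 0.15, sucB of the citric acid cycle 0.41 ± 0.24, aceK, which switches flow into the glyoxylate shunt, 0.63 ± 0.40, and the chaperone genes dnaJ and groL 0.49 ± 0.35 and 0.42 ± 0.23. With 3B turned, the smallest p belonged to nuoK (0.47 ± 0.11) and atpB (0.37 ± 0.10), to aceK (0.33 ± 0.28) and mdh (-0.16 ± 0.06), and to dnaJ (0.24 ± 0.33) and clpX (0.20 ± 0.12). None of these genes passed the gene test. Both energy lists lost their call without run 3 (adjusted p 0.0752 each), and heat shock without run 1 (0.453), without run 3 (0.0752), without array 1B (0.0533) and on the A arrays alone (0.136). The respiration list also lost it on the B arrays alone (median 0.07, adjusted p 0.535) and with the arrays turned by the labels' dyes (median 0.11, adjusted p 0.0885). Turned by the labels' dyes or channels, the citric acid cycle list fell to medians of 0.03 and 0.04 (adjusted p 0.66 and 0.831), and turned by the channels heat shock fell to 0.03 (adjusted p 0.973), each without a call.

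**Figure D3:**
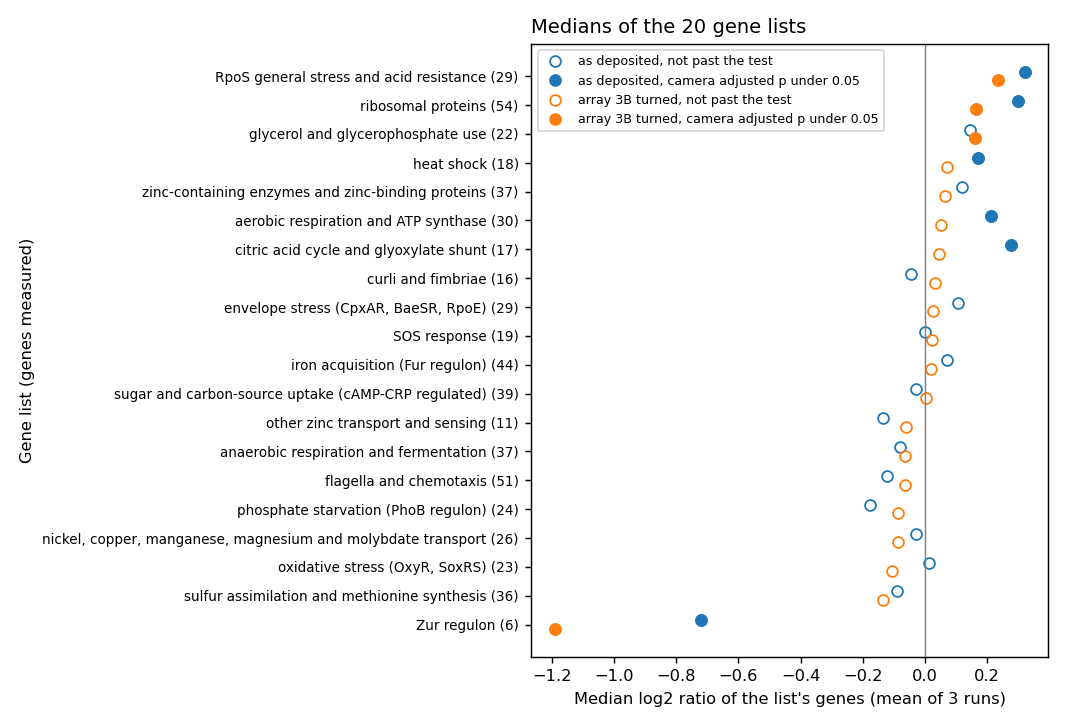
Median log2 ratio (x axis, mean of 3 runs) of the measured genes of each of the 20 lists (y axis, number of genes in brackets), as deposited (blue) and with array 3B turned (orange); filled points passed camera with a preset correlation at an adjusted p under 0.05 and open points did not. The Zur regulon lay at -0.72 and -1.19, and every other list's median was between -0.18 and 0.32.

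The other 13 lists passed in neither orientation. For each, the medians and camera adjusted p follow as deposited and with 3B turned, and then the members with the smallest p in each orientation, none of which passed the gene test over all genes. The 11 genes of other zinc transport and sensing had medians of -0.14 and -0.06 (adjusted p 0.266 and 0.59). As deposited, zntR, the regulator of zinc export, averaged -0.32 ± 0.38 and zraP -0.28 ± 0.37, and with 3B turned zur itself averaged -0.25 ± 0.23 and zntR -0.29 ± 0.39. The 37 genes of zinc enzymes and zinc-binding proteins had medians of 0.12 and 0.07 (0.0606 and 0.0724), led by dnaJ (0.49 ± 0.35) and frmA (0.41 ± 0.26) as deposited and by pyrI (0.30 ± 0.02), the zinc-binding chain of aspartate carbamoyltransferase, and frmA (0.36 ± 0.33) with 3B turned. Among other metals, the 44 iron acquisition genes had medians of 0.07 and 0.02 (0.267 and 0.59). feoA of ferrous iron uptake averaged 0.69 ± 0.22 and exbB 0.85 ± 0.60 as deposited, and fepA, the outer membrane receptor for enterobactin, -0.71 ± 0.26 and efeO 0.48 ± 0.08 with 3B turned. The 26 genes of nickel, copper, manganese, magnesium and molybdate transport had medians of -0.03 and -0.09 (0.31 and 0.0856). copA, the copper-exporting ATPase, averaged -0.71 ± 0.53 and -0.79 ± 0.45, with cueO, a copper oxidase, at -0.53 ± 0.49 as deposited and nikC of nickel uptake at -0.58 ± 0.26 with 3B turned.

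Sulfur assimilation and methionine synthesis, 36 genes, had medians of -0.09 and -0.13 (camera adjusted p 0.928 and 0.0522), although as deposited the mean over genes was above 0, at 0.03. As deposited, 6 of its 8 members with an unadjusted p under 0.05 were above 0, led by the cysteine genes cysI (0.81 ± 0.28) and cysK (1.02 ± 0.56). With 3B turned, all 5 such members were below 0, led by metR (-0.78 ± 0.07), the regulator of methionine synthesis, and metF (-0.71 ± 0.67), and metR passed adjusted over the list alone. Phosphate starvation genes (24) had medians of -0.18 and -0.09 (0.161 and 0.0724), led by ytfK (0.49 ± 0.46) and phnK (-0.50 ± 0.48) as deposited and by phnO (-0.41 ± 0.33) and phnH (-0.42 ± 0.44) with 3B turned. The 51 flagellar and chemotaxis genes had medians of -0.12 and -0.06 (0.0772 and 0.246), led by tap (-0.50 ± 0.30) and flgH (-0.49 ± 0.29) as deposited. With 3B turned, 2 flagellar genes with an unadjusted p under 0.05 were above 0 and 2 below, led by fliA (0.49 ± 0.13), the flagellar sigma factor, and flgL (-0.67 ± 0.50).

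Envelope stress genes (29) had medians of 0.11 and 0.03 (camera adjusted p 0.161 and 0.499), with rpoE (0.63 ± 0.46) and rseA (0.41 ± 0.26), the envelope stress sigma factor and its inhibitor, first as deposited and rseC (0.45 ± 0.71) and acrD (0.32 ± 0.41) with 3B turned. The 23 oxidative stress genes had medians of 0.01 and -0.10 (0.928 and 0.143), with marR (-0.39 ± 0.15) and soxR (-0.27 ± 0.10) first as deposited and katG (-0.29 ± 0.18), a catalase gene, and ahpC (-0.52 ± 0.79) with 3B turned. As deposited their mean was below 0, at -0.02. Anaerobic respiration and fermentation, 37 genes, had medians of -0.08 and -0.06 (0.317 and 0.2). hyaC of hydrogenase 1 averaged -0.74 ± 0.65 and -0.80 ± 0.62, with hyaE (-0.36 ± 0.08) next as deposited and fdnG (-0.65 ± 0.82) with 3B turned. The 19 SOS genes had medians of -0.00005 and 0.02 (0.929 and 0.928), with dinI at -0.39 ± 0.15 and -0.36 ± 0.19 and uvrD at 0.39 ± 0.40 and 0.40 ± 0.40. The 16 curli and fimbriae genes had medians of -0.04 and 0.03 (0.548 and 0.662), with fimA (0.51 ± 0.60) and fimD (-0.34 ± 0.24) as deposited and fimG (-0.47 ± 0.25) and csgB (0.59 ± 0.51) with 3B turned. The 39 sugar uptake genes had medians of -0.03 and 0.003 (0.928 and 0.814), with manX (0.49 ± 0.37) and rbsB (-0.33 ± 0.06) as deposited and rbsB (-0.23 ± 0.12) and srlB (0.30 ± 0.37) with 3B turned.

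Several genes were named in advance. In the mdtABCD-baeSR operon, which encodes a multidrug efflux system and a sensor of envelope stress, mdtD (b2077) averaged -0.57 ± 0.73 as deposited and -0.47 ± 0.84 with 3B turned, mdtA (b2074) -0.35 ± 0.48 and -0.16 ± 0.16, mdtB (b2075) 0.01 ± 0.40 and -0.08 ± 0.42, baeS (b2078) 0.33 ± 0.22 and 0.23 ± 0.39, and baeR (b2079) 0.14 ± 0.16 and -0.05 ± 0.18. mdtC (b2076) averaged 0.07 ± 0.29 as deposited and 0.00 with 3B turned (SD 0.25). fliD (b1924), the flagellar cap gene, averaged -0.24 ± 0.10 and -0.18 ± 0.16. The genes of the zinc-binding ribosomal proteins L31 and L36, rpmE (b3936) and rpmJ (b3299), averaged 0.18 ± 0.12 and -0.04 ± 0.14 as deposited and 0.21 ± 0.10 and -0.08 ± 0.18 with 3B turned. None of these genes passed the gene test (adjusted p between 0.581 and 0.997).

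The difference between arrays A and B of a run gives a technical background, if both arrays of a run carried the same RNAs, which is taken here and not stated in the labels. With 3B turned, the ribosomal protein genes differed by a median of 0.84 (camera adjusted p 3.05e-07), aerobic respiration by 0.58 (5.94e-05), the RpoS and acid resistance genes by 0.61 (0.00655) and the citric acid cycle by 0.54 (0.0137). As deposited the medians of these 4 lists were 0.38 (1.33e-05), 0.29 (0.0405), 0.31 (0.0284) and 0.08 (0.831), and sulfur assimilation and methionine synthesis differed by -0.29 (0.0294). The Zur regulon differed by -0.59 as deposited (adjusted p 0.204) and by 0.34 with 3B turned (adjusted p 0.475), where the orientation chosen from these genes partly sets the value. Single genes past an adjusted p of 0.05 in limma numbered 0 in both orientations, with 1190 at an unadjusted p under 0.05 with 3B turned and 360 as deposited, against 213.6 by chance. The fit without moderation called 1 gene with 3B turned and 0 as deposited. An A minus B difference of at least 1 on the log2 scale with an unadjusted p under 0.05 was seen for 642 genes with 3B turned and 211 as deposited. As deposited, 1 gene passed the adjusted test without run 1 and 2 without run 2.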

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

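The tests of why arrays 3B and 1B differ from the others, and every test with array 3B turned that uses an estimated correlation, were chosen after the result was seen, whereas the tests for a dye remainder, for single runs, for neighbouring genes and of other sign patterns were laid down before their outcome. A gap test for 1 array far from the other 5, which chance meets in about 1 of 20 genes, was run on 29 named genes and singled out 5, 4 of them on array 3B. The gap as a share of the range was 0.798 for zinT on array 3B (2.86 there) and 0.718 for znuA on array 3B (2.39). It was 0.799 for melR on array 3B (4.13), 0.664 for baeR on array 3B (0.58) and 0.653 for mdtC on array 1B (-0.59). Part of the 29 genes were named for their values here, melR among them. The signs of zinT and znuA on array 3B led to turning it. The rate of 1 in 20 is therefore no measure of chance for this count.

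The first pattern is the opposite sign of zinT, znuA, ykgM and pliG on array 3B. Noise on that array is argued against by the mean size of all 6 measured Zur genes there, znuB and znuC included, 1.44. No random list of 6 genes on that array reached it (permutation p = 1e-04, the smallest it can give). This test followed the sight of large ratios there, and random lists do not model noise of dim spots, as signal was not examined. A reversed response of the run 3 cultures is argued against by the mean of these 6 genes on array 3A, -1.13 ± 0.37 (SE over genes). It has the sign of runs 1 and 2. An exchange of the RNAs with the ratio turned as in runs 1 and 2 is argued against by the correlation, across genes, of array 3B with the A minus B part of those runs, 0.442, which lies above 0 as an unturned dye swap would give. Array 3B may thus hold a dye swap whose ratio was left unturned, and the correlation of -0.232 between array 1B and the dye part of runs 2 and 3 is in line with dyes on array 1B that were exchanged relative to its labels. Since Zur is known to release its genes when zinc is scarce, a ratio below 0 on the other 5 arrays may mean more RNA in zinc-limited cells, a hypothesis that rests on textbook knowledge and that these files cannot test independently.

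The second pattern is the position of the ribosomal protein and RpoS lists above 0 with array 3B turned, while both also differ between arrays A and B. Whether a dye effect left in the run means is the cause stays undecided: regressing each run's values on its A minus B part left camera's p at 1.93e-06 and 2.27e-06, but it moved the list medians only from 0.164 to 0.156 and from 0.237 to 0.240, less than their bootstrap SE of 0.027 and 0.058, so the bound set beforehand decided nothing. Correlation among the genes of each list remains open and may account for these calls. Its estimates were 0.103 (ribosomal proteins) and 0.17 (RpoS), both above camera's preset. With an estimated correlation camera's p was 0.135 and 0.152, but this test can lose a call without correlated genes. For the glycerol list it gave 0.0809 against 0.00271 with the preset, although the estimated correlation there was -0.043, below the preset. A shared fluctuation of a few runs could give these shifts, but the lost calls alone do not show one. Whether 1 run carries them is undecided, because the smallest run medians, 0.066 ± 0.042 and 0.062 ± 0.049 (bootstrap SE over genes), both in run 3, lie near 0. An effect of zinc limitation remains among the open explanations and its direction is not settled.

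The third pattern is that genes next to one another on the chromosome had similar mean ratios with 3B turned. Neighbouring genes are often printed at the same position of different print blocks, and such pairs (2536) correlated at 0.192 against 0.0991 for other neighbours (989 pairs), a difference of 0.0928 ± 0.0411 (bootstrap SE), so spot position may add to the similarity. Neighbours printed at different positions still correlated above 0, at 0.0991 (permutation p = 0.0014), as shared transcription would give. Position and transcription are both open for the first kind of pair, and a single neighbouring group with like ratios is weak evidence of an operon response on these arrays.

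The 4 possible sign patterns of the 3 run means are too few for a share under 0.05. As deposited, the count of genes past the adjusted p was 0 in the real pattern and at most 0 in the others, a tie over 4 of 4, and the count of at least 2-fold was 9 against at most 17, reached or exceeded by 2 of 4 patterns. With 3B turned, the counts were 1 against at most 1 (2 of 4 patterns) and 10 against at most 9 (1 of 4).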

How the results depend on the processing

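Every setting with array 3B turned, array 3B left out or print blocks centred was chosen after the data were seen. As deposited, the count of genes past the adjusted p was 0 under the other settings, replicate block included, and 1 (zinT) with array 3B left out or turned. The count of at least 2-fold (9) was 132 on the A arrays, 30 on the B arrays, 29 without array 1B, 20 without 3B, 16 turned by the labels' channels and 36 to 41 without a run. The 6 lists past camera became 3 to 5 without a run and 0 with an estimated correlation or fry. The Zur median of -0.72 stayed below 0, but its call was lost on the B arrays (-0.45), by the labels' channels (-0.30) and with an estimated correlation or fry (value -0.7214 unchanged), and the median ran from -1.29 to -0.37 without a run. With 3B turned, the 1 gene became 3 with all 6 arrays and the run as a replicate block (zinT, znuA and 3.3.10.8), 0 on the A arrays, without 1B or without moderation, and 0 to 3 without a run. The at least 2-fold count (10) was 132 on the A arrays, 70 on the B arrays, 20 without 3B and 11 to 36 without a run. The 4 lists became 7 with features tested singly, 0 with an estimated correlation or fry and 3 to 7 without a run. The Zur median of -1.191 kept its value with an estimated correlation and fry but lost its call, and was -1.29 to -0.97 without a run. On the B arrays alone the ribosomal median turned to -0.22 and the RpoS median to -0.13. A minus B calls numbered 0 to 2 without a run. The cause of these changes was not tested, except that fewer arrays enter when some are left out. Runs are paired by design within each array; the correlation of a run's arrays in the block fit was -0.068 as deposited and -0.31 with 3B turned. Of 963 alternatives for named genes and other lists, 915 kept their side of the threshold, 41 lost a call, 5 gained one and 2 reversed, and in 50 a named gene's uncalled value changed sign. Many of the 963 had no call to lose. Of the called lists, glycerol use with 3B turned lost its call in 8 and kept it in 7. Heat shock as deposited lost it in 8 and kept it in 13, and RpoS as deposited lost it in 2 and kept it in 19. Camera takes no block, so the block settings were not run for lists. Both missing-value settings and the setting with no array turned left all values as they were, since no value was missing on some arrays only. Signal over background was not examined.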

Other observations

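The tests in this part were chosen after the data were seen, and the genes below were picked for their values. Outside the Zur list, several genes had the same sign on all 6 arrays once array 3B was turned. The named genes farthest from 0 were yjeN (-1.14), uhpB (-1.07), yffL (-0.87), ycaD (-0.83) and hyaC (-0.80). Nearer to 0 were copA, the exporter of copper (-0.79), metR (-0.78) and fepA (-0.71). Above 0 were pykF, a pyruvate kinase gene, at 0.76, iscR, the regulator of iron-sulfur cluster assembly, at 0.66, and thiI, which acts in thiamine and tRNA sulfur transfer, at 0.66. The unnamed feature 3.3.10.8 followed the Zur genes, with ratios between -2.17 and -0.50 on 5 arrays and 1.47 on array 3B. None of these passed the adjusted test (adjusted p between 0.25 and 0.892). Genes with one sign on all 6 arrays numbered 112 with 3B turned, against 133.5 if the signs on the arrays were independent, which the correlations between arrays rule out, so no chance value is given for this count.

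Of the 32 possible sign patterns over the 6 arrays, the one with 1B and 2B opposite to 1A, 2A, 3A and 3B was the most frequent, with 781 genes. A dye effect would give this pattern if the ratios of 1B and 2B had been turned and that of 3B had not. The deposited orientation had 191 genes with one sign throughout, the labels' dyes 106 and the labels' channels 133. The run means of runs 1 and 2 correlated across genes at 0.049. The pairs of run 3 with runs 1 and 2 correlated at 0.157 and 0.171 as deposited and less, at 0.023 and 0.088, with 3B turned. Without the Zur genes the 3 values were 0.027, 0.161 and 0.173 as deposited and 0.027, -0.009 and 0.062 with 3B turned. If 3B is an unturned dye swap, a dye part stays in the deposited mean of run 3 and cancels when 3B is turned. A dye part shared with runs 1 and 2 could then raise the deposited values, which was not tested. The higher values are therefore no evidence for the deposited orientation.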
